A study of Mus musculus with 35 samples.

How the data were processed

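Poly(A) RNA was measured in 35 libraries of N2a Flp-In rtTA mouse neuroblastoma cells, from 2 lines, 3 conditions and 3 fractions with 2 biological replicates per group, of which 1 group has 1 library. Per the labels' protocols, cells were transfected with a single Chtop siRNA product or a non-targeting pool, doxycycline was added with the medium change at 24 h for the rescue, and cells were harvested at 72 h. Per the same protocols, cells were counted, equal numbers were taken, 20% was kept as the total sample, and the rest was parted into nuclei and cytoplasm. The control came from 2 and the other conditions from 3 culture dishes. No library had doxycycline with the control siRNA, so an effect of doxycycline or of the tagged protein alone is not separated from rescue. No spike-in RNA is named in the labels, so every change is relative to the typical gene of the fraction. The siRNA sequence is not given in the sources used here.

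Per the submitters' processing notes, Salmon 0.14.1, DESeq2 (version not given) and the mm10 genome were used. The deposited counts are whole numbers for 9239 genes, and what the authors did to choose these genes is not stated. The deposited RPKM values cover 54393 genes and, per the file headers, are reads scaled to transcript length and library size. They were used only for 45154 genes outside the count table, and 1 RPKM column with no sample among the labels was not used. The authors' normalized counts, a signal scale made with DESeq2 per the file headers, are not the counts divided by 1 factor per library and were not tested here. The deposited log2 fold changes between fractions and the differences of these, with gene marks at stated limits, come from the authors' tables and are cited only where credited to the authors' deposited table. That table also marks genes that overlap Chtop iCLIP, with no source stated. Gene positions came from GENCODE M21 on mm10.

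Counts were tested with edgeR 4.0.16 under R 4.3.3. For each fraction, and for nuclei with cytoplasm together, genes were kept by filterByExpr (2, 0, 1 and 0 genes removed), scaled by TMM and fitted by group with robust quasi-likelihood dispersion. Adjusted p-values are Benjamini-Hochberg over all genes of a fit, with calls under 0.05. The SE of a log2 fold change is its size divided by the root of the F statistic. The comparisons were knockdown against control over both lines and by line, each rescue against its knockdown, the difference of each between the lines, nuclei against cytoplasm under control siRNA, and the same contrasts of the nuclear to cytoplasmic ratio, called shift. The cytoplasmic pEx5 control, with 1 library, is assumed to vary like the other groups. P-values measure the spread between the replicates, which the labels call biological. Depth per library is given with the data description. Median SE was 0.084 for the knockdown in total lysate and 0.15 for its shift.

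Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. Of 33 lists written before the data were examined, 29 had at least 5 tested members. Of 348 pairs of list and contrast 46 passed, and 3 of these held with an estimated correlation: cholesterol genes in the nuclear knockdown and, between control fractions, nuclear noncoding RNAs and detained-intron genes. With the replicate block and an estimated correlation, a setting chosen after seeing the data, only the detained-intron genes still passed, at 0.0097 against 0.21 and 0.14 for the others. The genes named were fixed by rule before the data were examined: Chtop, the 10 highest and 10 lowest log2 fold changes per contrast among called genes with a mean of at least 5 CPM and the same sign in both lines, and up to 4 members of each list that passed or held called genes. Symbols of predicted genes were passed over.

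Alternatives chosen before the data were examined were DESeq2 1.42.0, its size factors in edgeR, library totals alone, no filter, the replicate number as a block, the culture as a block, all 35 libraries in 1 fit, and each library left out. Alternatives chosen after seeing the data were leaving out genes with a 7-base sequence in the 3' UTR, taking out each library's trend on transcript length and GC, the same with the block, and taking out its trend on the nuclear to cytoplasmic control ratio of the other line. The rescue against control was also added then. Replicate numbers come from the labels, and the protocol makes the fractions of a culture share cells. Residuals of libraries with the same number had correlations of 0.35 to 0.79 in total lysate (15 pairs), 0.52 to 0.72 in nuclei (15 pairs) and 0.059 to 0.65 in cytoplasm (10 pairs), and of -0.089 to 0.50 between nuclei and cytoplasm of 1 line and condition (5 pairs).

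All 7-base sequences found in the 3' UTRs of at least 50 genes were tested by linear regression of the log2 fold change on their presence, with 3' UTR length and GC held fixed, over 8633 genes with a 3' UTR of at least 100 bases. The steps were tested on simulated data. Of 50 genes changed by 2-fold, 100% were recovered for the knockdown in total lysate, 96% for the pEx5 rescue in total lysate, 98% for the knockdown shift and 60% for the pEx5 rescue shift. At 1.5-fold these were 96%, 58%, 36% and 12%. Unchanged genes gave 5, 12, 7 and 6 false calls. Camera passed the planted set and 1 of 20 sets in all, and the 7-base search found its planted sequence in 20 of 20 runs.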

Results

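Poly(A) RNA was sequenced from 35 libraries of mouse N2a neuroblastoma cells. The cells came from 2 Flp-In lines, each with a doxycycline-inducible FLAG-Chtop cDNA that the siRNA cannot target: the mEx5 line, whose cDNA lacks exon 5, and the pEx5 line, whose cDNA holds it. Chtop is an RNA-binding protein that works with the TREX complex in mRNA export. Each line was measured under 3 conditions (a non-targeting siRNA pool as control, a Chtop siRNA as knockdown, and the Chtop siRNA with doxycycline as rescue) and in 3 fractions (total lysate, nuclei and cytoplasm). This made 18 groups of 2 biological replicates, except that the cytoplasmic control of the pEx5 line had 1 library. Counts per library summed to between 20652832 and 36102129 in total lysate, 11681781 and 28705620 in nuclei and 19478702 and 40105458 in cytoplasm. Values are CPM, counts scaled to the library total, as mean ± SD, and changes are log2 fold changes with their standard error (SE), from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

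Chtop (ENSMUSG00000001017.15, chromosome 3, 90498956 to 90509498, minus strand, mm10) was lower in every knockdown library than in every control library of its fraction and line, which answers whether the siRNA worked. In total lysate, control libraries held 139 ± 0.195 CPM in the mEx5 line and 130 ± 6.92 in the pEx5 line (n = 2 each). The knockdown left 33.5 ± 1.78 and 20.9 ± 1.50 CPM. The fall was 5.13-fold over both lines (log2 fold change -2.36, SE 0.12, edgeR adjusted p = 3.6e-06), with line values of -2.06 and -2.66. In nuclei the level went from 124 ± 7.24 to 66.1 ± 6.37 CPM in the mEx5 line and from 105 ± 13.95 to 58.4 ± 1.55 CPM in the pEx5 line. That was a 1.79-fold fall (log2 -0.84, SE 0.11, edgeR adjusted p = 5.9e-04). In cytoplasm it went from 142 ± 7.99 to 28.7 ± 3.59 CPM and from 137 (n = 1) to 19.1 ± 1.99 CPM, a 6.19-fold fall (log2 -2.63, SE 0.094, edgeR adjusted p = 4.1e-08). With doxycycline, mean Chtop counts lay above the control mean in every fraction: 204 ± 24.8 and 243 ± 54.6 CPM in total lysate, 259 ± 13.9 and 262 ± 56.3 in nuclei, and 184 ± 11.8 and 192 ± 16.5 in cytoplasm. Against control siRNA the rescued level in total lysate was 1.43-fold higher in the mEx5 line (log2 0.52, SE 0.15, edgeR adjusted p = 0.041) and 1.87-fold higher in the pEx5 line (log2 0.90, SE 0.15, edgeR adjusted p = 0.0041). In cytoplasm this difference was not called (edgeR adjusted p = 0.072 and 0.067). The counts do not separate cDNA from endogenous Chtop reads.

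**Figure D1:**
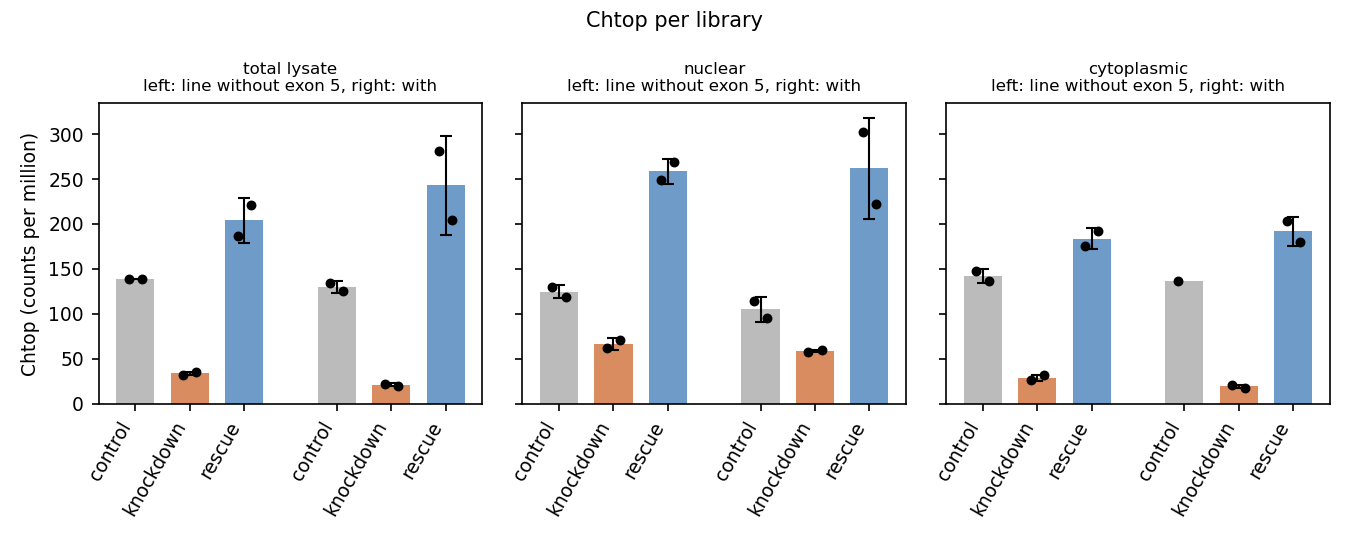
Chtop in CPM (vertical axis) in each of the 35 libraries by line, condition and fraction, with points for libraries, bars for group means and whiskers of 1 SD. The knockdown libraries lie below all control libraries of their fraction and line, at 19.8 to 34.7 CPM in total lysate.

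Nuclear and cytoplasmic libraries under control siRNA were compared first, to ask how well the fractions were parted. Over all conditions, mitochondrial transcripts made up 0.63 to 1.61% of counts in nuclear libraries and 1.90 to 3.31% in cytoplasmic ones. The nuclear libraries were thus not free of them. RNAs known to stay in the nucleus were nuclear here. Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672, minus strand), a noncoding RNA of nuclear speckles, was 18.3-fold higher in nuclei, at 892 ± 106 against 50.6 ± 6.23 CPM (n = 4 and 3). Its log2 ratio was 4.19 (SE 0.14, edgeR adjusted p = 8.5e-12). Neat1, the scaffold RNA of paraspeckles, had a log2 ratio of 3.55 (SE 0.37, edgeR adjusted p = 4.8e-07). Of 33 genes known for introns detained in the nucleus, 31 were higher in nuclei and 0 lower, with Ccnl2 at 2.90 and Nktr at 2.27. For this list the camera adjusted p was 3.1e-19, 0.014 with an estimated correlation and 0.0097 with this and the replicate number as a block. Of 7 nuclear long noncoding RNAs, 6 were higher, with a camera adjusted p of 2.2e-04, 0.032 with an estimated correlation and 0.14, no longer a pass, with this and the block. Among 206 zinc finger genes 137 were higher in nuclei and 16 lower, including Zfp692 at 2.75. The camera adjusted p was 2.5e-07, and 0.89 with an estimated correlation. Noncoding snoRNA host genes were higher in 8 of 12 cases, with Gas5 at 1.52. Their camera adjusted p was 0.023, 0.89 with an estimated correlation and 0.055 without nuclear mEx5 control replicate 1, 0.089 with all 35 libraries in one fit and 0.086 with the control-ratio trend taken out.

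Among the mRNAs lower in nuclei than in cytoplasm was Tmsb10, an actin-binding thymosin, with a log2 ratio of -1.51 (SE 0.19, edgeR adjusted p = 4.0e-06). Tpt1 had -1.36 and Ybx1 -1.35. Ribosomal protein mRNAs were lower in nuclei in 64 of 78 cases and higher in 5, with Rps4x at -1.29 and Rplp0 at -1.24 (camera adjusted p = 1.1e-09, and 0.89 with an estimated correlation). Nuclear-encoded respiratory chain mRNAs were lower in 32 of 38 cases and higher in 0, with Ndufa8 at -1.02 (camera adjusted p = 2.1e-05, and 0.89 with an estimated correlation). Adjusted over the list alone, 31 detained-intron, 6 noncoding, 138 zinc finger and 8 snoRNA host genes were higher, and 65 ribosomal protein and 34 respiratory chain genes lower. In all, 3125 genes were higher in nuclei and 3336 in cytoplasm. A level of at least 2-fold was reached by 1011 and 243 of them.

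The next comparison asked what loss of Chtop did to steady-state RNA, from knockdown against control in total lysate over both lines (n = 4 libraries each). It raised 1973 genes and lowered 2084 of 9237, most of them mildly: 81 rose and 120 fell by at least 2-fold. Fndc10 (ENSMUSG00000074738.2, chromosome 4, 155694342 to 155696481, plus strand) rose 4.67-fold, to 35.8 ± 2.10 against 7.62 ± 0.930 CPM (log2 fold change 2.22, SE 0.092, edgeR adjusted p = 1.6e-06). Skida1 (ENSMUSG00000054074.9, chromosome 2, 18040676 to 18049051, minus strand) rose 3.21-fold, and Gid4, a substrate receptor of the CTLH ubiquitin ligase, 2.81-fold. The histone genes H2afj and Hist3h2ba followed at log2 1.70 and 1.75, and Rn7s1, the 7SL RNA of the signal recognition particle, at 2.22 (SE 0.33). Gnai2 (ENSMUSG00000032562.13, chromosome 9, 107614125 to 107635367, minus strand), an inhibitory G protein subunit, fell 3.62-fold, to 68.4 ± 11.7 against 245 ± 5.32 CPM (log2 fold change -1.86, SE 0.096, edgeR adjusted p = 3.6e-06). Ptgs1 (ENSMUSG00000047250.13, chromosome 2, 36230426 to 36252272, plus strand), cyclooxygenase 1, fell 4.01-fold, to 26.4 ± 12.9 against 103 ± 38.3 CPM. Tuba8, an alpha tubulin, fell 3.49-fold, and Rnh1, the ribonuclease inhibitor, and Abat, the GABA transaminase, had log2 values of -1.66 and -1.63. Ctla2a and its close copy Ctla2b, at -1.84 and -1.70, can share reads, as can the histone genes and Rn7s1 with their copies.

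Cholesterol synthesis and uptake genes fell together after knockdown: 20 of 24 were lower and 1 higher in total lysate, with a median of -0.58. Tm7sf2 at -1.16, Dhcr7 at -1.01 (SE 0.093, edgeR adjusted p = 3.9e-05), Msmo1 at -0.80 and the squalene synthase Fdft1 at -0.71 were among them (camera adjusted p = 7.1e-11, and 0.56 with an estimated correlation). S-phase genes rose in 14 of 28 cases and fell in 0, including the cell cycle regulator E2f1 at 0.55, Cdc45 at 0.44 and Mcm4 at 0.41 (camera adjusted p = 0.0046, and 0.82 with an estimated correlation). Zinc finger genes rose in 72 of 206 cases and fell in 17, with Zfp651 at 0.98 and Zfp362 at -0.68 (camera adjusted p = 0.0025, and 0.82 with an estimated correlation). Adjusted over the list alone, 20 cholesterol genes were lower and 1 higher, 16 S-phase genes higher, and 72 zinc finger genes higher and 17 lower. The other 26 lists did not pass, with camera adjusted p from 0.084 to 0.96. Members that changed on their own included the neuronal growth protein Dpysl3 at -1.48, the secretory granule proteins Chgb at -1.06 and Vgf at -0.89, the glucose transporter Slc2a3 at -1.19 and the endoplasmic reticulum chaperone Pdia6 at -1.35. Pdia6 went against most of its list, in which 9 of 21 chaperones rose and 3 fell, with a median of 0.15 (camera adjusted p = 0.32). Of 34 mRNA export factors other than Chtop, 7 rose and 3 fell (camera adjusted p = 0.28). Mitochondrial transcripts had a median of 0.43, positive for 14 of 15, with 1 called (camera adjusted p = 0.23, 0.031 with the replicate number as a block, and 0.71 with the block and an estimated correlation).

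The 2 lines, whose cDNAs were not induced in these libraries, gave the knockdown a repeat. Their changes in total lysate had a Spearman rho of 0.91 across 9236 genes, which are not independent replicates. Called on its own, the mEx5 line had 1014 genes higher and 1173 lower and the pEx5 line 1096 and 1261. Both lines called 1743 genes in the same direction and 0 in opposite directions, where independent lists would share 280. These counts lean on single libraries: the mEx5 count of 2187 became 928 without control replicate 1, 821 without control replicate 2 and 1078 without knockdown replicate 1, and the pEx5 count of 2357 became 917 without control replicate 2 and 1012 without knockdown replicate 1. With the replicate number as a block they were 4307 and 4467. For the difference of the knockdown between the lines, edgeR called 0 genes with or without the block, and DESeq2 called 0. Without the block 112 genes had an unadjusted p under 0.05 where 462 would be expected by chance. These p-values thus ran high, so 0 calls do not show that the lines were alike.

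In nuclei, knockdown against control asked which RNAs changed where Chtop acts. It raised 1425 and lowered 1478 genes (n = 4 libraries each). Skida1 rose 4.48-fold (log2 fold change 2.16, SE 0.14, edgeR adjusted p = 5.1e-05). Mbd6 (ENSMUSG00000025409.14, chromosome 10, 127281956 to 127289018, minus strand), a methyl-CpG-binding-domain protein, went to 930 ± 34.1 against 307 ± 33.3 CPM, and Rdm1 and Fndc10 had log2 values of 2.02 and 1.83. Tuba8 at -1.91, Ptgs1 at -1.82 and Abat at -1.59 were among the lowest, with Ier3 at -1.50 and the phosphatase Dusp4 at -1.49. Cholesterol genes fell in 19 of 24 cases and rose in 0, with Msmo1 at -1.01 and Pmvk at -1.19. Camera gave the list an adjusted p of 2.0e-12, 0.0079 with an estimated correlation and 0.21, no longer a pass, with this and the replicate number as a block. Detained-intron genes rose in 9 of 33 cases and fell in 2: Mat2a, an enzyme of S-adenosylmethionine synthesis, reached 1.23 and the splicing kinase Clk2 0.81 (camera adjusted p = 0.013, and 0.60 with an estimated correlation). Zinc finger genes rose in 51 of 206 cases and fell in 9, and S-phase genes rose in 10 of 28 and fell in 0, with camera adjusted p of 3.9e-04 and 0.0038. With an estimated correlation these p-values were 0.75 and 0.87. Immediate-early genes fell in 9 of 26 cases and rose in 2, with Junb at -0.78 and Maff at -0.94 (camera adjusted p = 0.023, and 0.48 with an estimated correlation). Noncoding snoRNA hosts rose in 5 of 12 cases, with Snhg20 at 1.61. Their camera adjusted p was 0.023, 0.60 with an estimated correlation and 0.071 without nuclear mEx5 control replicate 2, 0.056 without nuclear pEx5 control replicate 2 and 0.14 with all 35 libraries in one fit. Adjusted over the list alone, 21 cholesterol and 10 immediate-early genes were lower, and the other counts stayed as given. With the replicate number as a block, 2571 genes were higher and 2552 lower, and late activity genes and noradrenergic neuroblastoma genes also passed (camera adjusted p = 0.045 and 0.011, against 0.089 and 0.063 without the block). With the block and an estimated correlation these were 0.45 and 0.45.

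The cytoplasmic comparison asked which RNAs changed after export. It raised 1832 and lowered 1931 of 9238 genes (n = 4 knockdown and 3 control libraries). Fndc10 had a log2 value of 2.16 and Gid4 of 1.62 (SE 0.095, edgeR adjusted p = 1.1e-06). The long noncoding RNA Tug1 rose by 1.35. Gnai2 at -1.90 (SE 0.091, edgeR adjusted p = 2.9e-07), Procr, a protein C receptor, at -1.93, the cathepsin inhibitor Cstb at -1.60 and S100a10 at -1.57 were among the lowest after Chtop. Ribosomal protein mRNAs fell in the cytoplasm in 42 of 78 cases and rose in 0, with a median of -0.28, Rpl12 at -0.69 and Rpl28 at -0.59 (camera adjusted p = 1.9e-06, and 0.77 with an estimated correlation). In total lysate 7 of the 78 were lower and 1 higher. Cholesterol genes fell in 19 of 24 cases and rose in 1 (camera adjusted p = 2.9e-08, and 0.69 with an estimated correlation). Zinc finger genes rose in 91 of 206 cases and fell in 11 (camera adjusted p = 1.9e-06, and 0.62 with an estimated correlation). Neuronal genes fell in 12 of 24 cases and rose in 3, with Dpysl3 at -1.53, the RNA-binding protein Celf4 at -0.69, the synaptic protein Snap25 at -0.68 and the filament protein Ina at 0.82 (camera adjusted p = 0.023, and 0.77 with an estimated correlation). S-phase genes rose in 12 of 28 cases and fell in 2. Their camera adjusted p was 0.023, 0.88 with an estimated correlation and 0.096 without cytoplasmic mEx5 control replicate 2 and 0.071 without cytoplasmic pEx5 knockdown replicate 1. Adjusted over the list alone, 46 ribosomal protein genes were lower, 92 zinc finger genes higher and 4 neuronal genes higher. With library totals as the only scaling the split was 2277 higher and 1547 lower, 59.5% of the calls against 48.7%. With the replicate block, mitochondrial transcripts and glycolysis and hypoxia genes also passed (camera adjusted p = 0.027 and 0.033, against 0.15 and 0.11 without it). With the block and an estimated correlation these were 0.80 and 0.80.

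**Figure D2:**
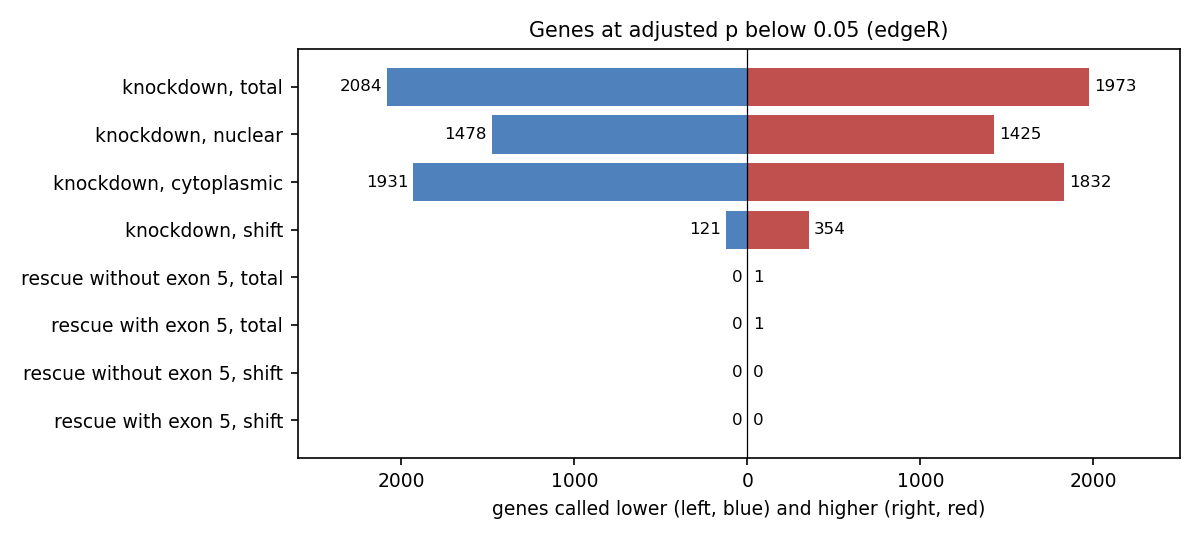
Number of genes called higher (right) and lower (left) at an edgeR adjusted p under 0.05 (bars). Shown are the knockdown in total lysate, nuclei, cytoplasm and the shift, and each rescue in total lysate and the shift. The knockdown bars reach 1973 and 2084 genes in total lysate, and the rescue bars in total lysate hold 1 gene each.

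Whether knockdown moved RNAs between nucleus and cytoplasm was asked from the nuclear to cytoplasmic ratio, knockdown against control (n = 8 and 7 libraries). The ratio rose for 354 genes and fell for 121. Mbd6 (ENSMUSG00000025409.14, chromosome 10, 127281956 to 127289018, minus strand) rose 2.51-fold (log2 fold change 1.33, SE 0.17, edgeR adjusted p = 5.3e-04). Chtop itself rose 3.49-fold in its ratio (log2 1.80, SE 0.15, edgeR adjusted p = 2.6e-05). Rdm1 at 1.83, Pias3, a SUMO ligase, at 1.27, the mitotic checkpoint ubiquitin ligase Chfr at 1.16 and the nuclear poly(A)-binding protein Pabpn1 at 1.07 rose too, as did the neuronal RNA-binding proteins Celf4 at 0.97 and Elavl3 at 0.86. The ratio fell for Gid4, -0.93 (SE 0.12, edgeR adjusted p = 5.8e-04), Plagl2 at -0.91, Akap9 at -0.90, Sesn2 at -0.81 and cyclin D3, Ccnd3, at -0.78. Ribosomal protein mRNAs had a median of 0.33, with 74 of 78 above 0, 4 called higher (with Rpl5 at 0.81 and Rpl10a at 0.75) and 0 lower (camera adjusted p = 1.7e-07, and 0.79 with an estimated correlation). The snoRNA hosts had a median of 0.44, with 3 of 12 called higher (camera adjusted p = 2.2e-04, and 0.79 with an estimated correlation). Immediate-early genes had a median of -0.31 with 0 of 26 called by edgeR (camera adjusted p = 0.0050, and 0.79 with an estimated correlation). Adjusted over the list alone, 4 ribosomal protein genes and 7 snoRNA hosts were higher.

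The balance of rises and falls in this ratio depended on scaling: 74.5% of calls were rises here, but with library totals alone the ratio rose for 206 genes and fell for 411, or 33.4% rises. The count of 475 became 247 without nuclear mEx5 control replicate 1, 288 without nuclear mEx5 knockdown replicate 1, 284 without nuclear pEx5 control replicate 2, 264 without nuclear pEx5 knockdown replicate 1, 247 without cytoplasmic mEx5 control replicate 1, 172 without cytoplasmic mEx5 knockdown replicate 1 and 314 without cytoplasmic mEx5 knockdown replicate 2. With each culture as a block there were fewer calls, 296 rises and 54 falls. With the replicate number as a block the count was 1188, from 766 rises and 422 falls. Mitochondrial transcripts then passed with a median of -0.47 (camera adjusted p = 0.0040, against 0.15 without it and 0.76 with the block and an estimated correlation). The 2 lines had a Spearman rho of 0.40 across genes for this shift, with 25 genes called in both, all in the same direction, where independent lists would share 0.376. Their trends with transcript length were opposite, with a Spearman rho of -0.54 in mEx5 and 0.12 in pEx5, and 0.63 for the difference between the lines. With length and GC trends taken out, chosen after seeing the data, 91.8% of the rises over both lines stayed called. The authors' deposited table marks 1555 genes as increased and 1239 as decreased in nuclear to cytoplasmic ratio after knockdown, at a log2 difference of 0.3. Of the 354 genes that rose here, it marks 339 as increased, and of the 121 that fell, 117 as decreased. Across genes its values and those computed here had a Pearson r of 0.92. The authors' values come from the same libraries, so the overlap and this r are not independent evidence. Their limit of 0.3 also lies below the median absolute shift of genes called here, 0.56. Conversely, of the 1555 genes marked as increased 339 were called as rises here, and of the 1239 marked as decreased 117 as falls.

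Genes that fell after knockdown were searched for shared 3' UTR sequence, to ask whether part of the change followed a short sequence match. Of 15989 7-base sequences, GAAAACT had the lowest t: the 1336 genes with it in their 3' UTR were lower by knockdown in total lysate than other genes (n = 8633 genes, difference -0.20, SE 0.011, t -17.7 over genes, Bonferroni p = 1.0e-64). The next were the overlapping AGAAAAC at t -11.0 and AAAACTA at t -10.2. All 3 occur in Chtop transcripts, as do 19.3% of the 7-base sequences tested, but not all at the same site. The one at t -11.0 is absent from the site given next, which also holds the one at t -10.2. GAAAACT lies in the coding sequence of the last exon of 7 Chtop transcripts, on the minus strand of chromosome 3 at 90499968 to 90499974. The difference was -0.082 (SE 0.011) in nuclei, -0.23 (SE 0.011) in cytoplasm and 0.15 (SE 0.0082) in the nuclear to cytoplasmic shift. Of 2009 genes with a searched 3' UTR that were lower in total lysate, 24.99% held the sequence, against 13.5% of genes not called and 10.1% of genes that rose. Gnai2, Dpysl3 and Rnh1 held it, but most of the largest falls did not. Of the 10 named genes with the lowest log2 values, 2 held it in total lysate, 1 in nuclei and 3 in cytoplasm. Of the 10 highest in each, 0 held it, and 3 had no searched 3' UTR. Over all searched genes 15.5% held it. For the ratio, 30.1% of rises and 5.88% of falls held it. Without the genes that hold it, 1624 genes rose and 1504 fell in total lysate, and the ratio rose for 189 genes and fell for 86, a setting chosen after seeing the data.

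**Figure D3:**
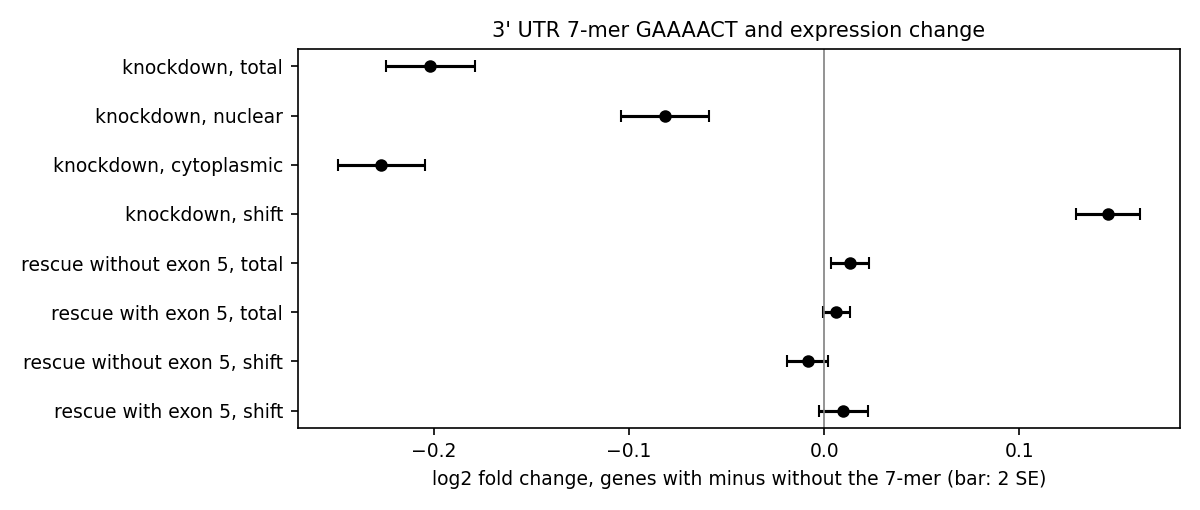
Difference in log2 fold change between genes with and without GAAAACT in their 3' UTR (horizontal axis), with bars of 2 SE over genes. Shown are the knockdown in total lysate, nuclei, cytoplasm and the shift, and each rescue in total lysate and the shift. The knockdown differences lie at -0.20 in total lysate, -0.082 in nuclei and -0.23 in cytoplasm, and those of the rescues in total lysate at 0.013 and 0.0062.

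Each rescue was compared with its knockdown to ask what the isoform restored. In total lysate edgeR called Chtop alone in either line. It rose 5.97-fold in mEx5 (log2 2.58, SE 0.16, edgeR adjusted p = 2.1e-04) and 11.8-fold in pEx5 (log2 3.56, SE 0.17, edgeR adjusted p = 1.4e-05, n = 2 against 2 each). At an unadjusted p under 0.05 there were 669 genes in mEx5 and 147 in pEx5, where 462 would be expected by chance. DESeq2 called 8 and 3. Chtop was also the only call in nuclei and in cytoplasm of either line, but the nuclear call in mEx5 ended without nuclear mEx5 knockdown replicate 1, and the cytoplasmic pEx5 count became 1735 without cytoplasmic pEx5 knockdown replicate 2. The cytoplasmic mEx5 count became 3 without either cytoplasmic pEx5 knockdown replicate. DESeq2 called 12 and 5 genes in nuclei and 5 and 35 in cytoplasm (mEx5 and pEx5), and edgeR with the replicate number as a block 84 and 17 in nuclei and 2 and 2 in cytoplasm. Of the blocked nuclear calls besides Chtop, 78 of 83 in mEx5 and 14 of 16 in pEx5 had the sign opposite to the other line's nuclear knockdown. For 41 and 6 of them that knockdown change was itself called. Skida1 (-0.83 and -0.76), Epm2aip1 (-0.73 and -0.89) and Stox2 (-0.51 and -0.61) fell in both. With the replicate number as a block, mEx5 had 23 higher and 39 lower genes and pEx5 3 higher in total lysate. Selenoo, a mitochondrial pseudokinase, rose by 0.91 (SE 0.12, edgeR adjusted p = 0.0017) in the blocked mEx5 rescue after a log2 of -1.28 by knockdown over both lines. H2afj at -0.58, Ctxn1 at -0.44 and Arhgef11 at 0.50 went against knockdown changes of 1.70, 1.19 and -0.70 over both lines. These changes, and that of Selenoo, share the mEx5 knockdown libraries with the rescue, so the opposite signs are not independent. Of the 61 genes besides Chtop, 54 had the sign opposite to the other line's knockdown. With length and GC trends taken out as well, chosen after seeing the data, the mEx5 count of 62 became 22, and the mEx5 rescue had a Spearman rho of 0.51 with transcript length across genes. In pEx5 the blocked calls besides Chtop were Selenoo at 0.93 (edgeR adjusted p = 9.4e-04) and Klhl36 at 0.59 (edgeR adjusted p = 0.050). These genes were chosen after their values were seen. An interval of 95% within 2-fold was found for 9012 genes in mEx5 and 9059 in pEx5.

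To read reversal over many genes, the genes called by knockdown in the other line were followed, so that no library was shared. In the mEx5 rescue, 1260 genes lower in the pEx5 knockdown had a median of 0.077, against -0.53 in that knockdown. Of these, 70.7% moved up (camera p = 1.3e-07, and p = 0.20 with an estimated correlation). The 1096 genes higher in the knockdown had a median of -0.040, and 60.9% moved down (camera p = 3.5e-04, and p = 0.15 with an estimated correlation). In the pEx5 rescue, 1172 genes lower in the mEx5 knockdown had a median of 0.078, and 79.9% moved up (camera p = 8.7e-15, and p = 0.10 with an estimated correlation). The 1014 genes higher in it had a median of -0.075, and 77.1% moved down (camera p = 1.0e-18, and p = 0.015 with an estimated correlation). These medians were 14.5%, 8.24%, 14.8% and 15.2% of the knockdown medians, with the opposite sign in both replicates. By replicate number (4, then 6), genes lower had medians of 0.14 and 0.026 in mEx5 and 0.13 and 0.030 in pEx5. Genes higher had -0.055 and -0.022 in mEx5 and -0.11 and -0.042 in pEx5. With the number as a block, on the sets called with it, the medians were 0.075, -0.048, 0.065 and -0.054. Leaving out 1 library unbalances the replicate numbers, so the medians below also carry the difference between them. The mEx5 median for genes lower became 0.028 without mEx5 knockdown replicate 1 and 0.15 without mEx5 knockdown replicate 2. For genes higher it became -0.022 without mEx5 rescue replicate 1, -0.065 without mEx5 rescue replicate 2, -0.019 without pEx5 knockdown replicate 1 and -0.076 without pEx5 knockdown replicate 2. The pEx5 median for genes lower became 0.0051 without pEx5 knockdown replicate 1, 0.16 without its replicate 2 and 0.045 without pEx5 rescue replicate 2. For genes higher it became -0.033 without pEx5 knockdown replicate 1 and -0.12 without its replicate 2.

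Each rescue comparison shares its knockdown libraries, on the opposite side, with the knockdown comparison over both lines. Spread in these libraries alone can thus give a list opposite signs in the 2. Among gene lists, S-phase genes, of which 14 of 28 were called higher after knockdown in total lysate, had values below 0 in the mEx5 rescue for 26 of 28. Their median was -0.16, with 0 called by edgeR (camera adjusted p = 5.3e-05, and 0.70 with an estimated correlation). In the pEx5 rescue 26 of 28 were below 0, with a median of -0.10. The camera adjusted p was 1.4e-04, 0.98 with an estimated correlation and 0.65 without total pEx5 knockdown replicate 1 and 0.61 without total pEx5 rescue replicate 2. Ribosomal protein mRNAs had a median of -0.12 in the mEx5 rescue (camera adjusted p = 5.2e-04, and 0.74 with an estimated correlation) and of 0.11 in the pEx5 rescue (camera adjusted p = 0.0012, and 0.98 with an estimated correlation). The mEx5 p-value was 0.19 without total mEx5 knockdown replicate 1 with the opposite sign, 0.20 without total mEx5 rescue replicate 2, 0.80 with length and GC trends taken out and 0.86 with these trends taken out and the replicate block. The pEx5 p-value was 0.99 without total pEx5 knockdown replicate 2 and 0.0079 without total pEx5 rescue replicate 1 with the opposite sign. Respiratory chain mRNAs had a median of -0.13 in the mEx5 rescue. Their camera adjusted p was 5.2e-04, 0.70 with an estimated correlation and 0.85 without total mEx5 knockdown replicate 1, 0.089 without total mEx5 rescue replicate 2, 0.21 with length and GC trends taken out and 0.16 with these trends taken out and the replicate block. With the replicate block, mRNA export factors passed in the mEx5 rescue with a median of -0.09 (camera adjusted p = 0.043, against 0.12 without it). Histone genes and snoRNA hosts passed in the pEx5 rescue with medians of -0.28 and 0.20 (camera adjusted p = 0.0012 and 0.037, against 0.057 and 0.13). With the block and an estimated correlation the p-values of these 3 lists were 0.73, 0.99 and 0.99, and edgeR called 0 members.

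Whether the isoforms differed in what they restored was asked from the difference between the rescues, the pEx5 line minus the mEx5 line. Each isoform was induced in 1 line only, and Chtop rose 5.97-fold in mEx5 and 11.8-fold in pEx5. A difference here, or in the shift below, therefore cannot be ascribed to exon 5 apart from line and Chtop level. In cytoplasm edgeR called 0 genes and DESeq2 called 7, all with a difference below 0, and in nuclei both called 0. In total lysate edgeR called 0 genes and DESeq2 called 0. At an unadjusted p under 0.05 there were 98 genes where 462 would be expected by chance. So 0 calls do not show that the isoforms acted alike. For 8762 genes of 9237 the 95% interval of the difference lay within 2-fold. Chtop differed by 0.98 (SE 0.22, edgeR adjusted p = 1.0). Ribosomal protein mRNAs had a median difference of 0.25, above 0 for 76 of 78 (camera adjusted p = 1.1e-10, and 0.93 with an estimated correlation). The p-value was 0.41 without total mEx5 knockdown replicate 1 and 0.27 without total pEx5 rescue replicate 1. Respiratory chain mRNAs had a median difference of 0.19, above 0 for 37 of 38 (camera adjusted p = 1.3e-07, and 0.93 with an estimated correlation). The p-value was 0.15 without total mEx5 knockdown replicate 1 and 0.13 without total pEx5 rescue replicate 1.

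Nuclear to cytoplasmic shifts were compared between rescue and knockdown to ask whether either isoform brought RNAs back to the cytoplasm. EdgeR called 0 genes in mEx5, with 99 at an unadjusted p under 0.05 and 2 by DESeq2, and 0 in pEx5, with 187 and 3. By chance 462 would be expected at an unadjusted p under 0.05, so 0 calls do not show that no RNA moved back. The ratio of Chtop had values of -0.76 (SE 0.21, edgeR adjusted p = 1.0) in mEx5 and -1.17 (SE 0.21, edgeR adjusted p = 0.26) in pEx5. Its counts do not separate induced cDNA from endogenous reads. The values for Chtop here thus do not show whether endogenous Chtop RNA moved back. In pEx5 Chtop was called without nuclear pEx5 rescue replicate 1 (log2 -1.42, edgeR adjusted p = 0.033), and with each culture as a block (log2 -1.19, edgeR adjusted p = 0.043). Rbm15, an RNA-binding protein linked to nuclear export and RNA methylation, was called in mEx5 without nuclear mEx5 knockdown replicate 1 (log2 -1.24, edgeR adjusted p = 0.043). DESeq2 called Rbm15 at -1.03 (adjusted p = 0.012) and Rpl26 at 1.24 (adjusted p = 0.021) in mEx5, and Chtop at -1.18 (adjusted p = 0.0017), Stox2 at -0.86 (adjusted p = 0.024) and Rbm15 at -1.07 (adjusted p = 0.0026) in pEx5. These genes were chosen after their values were seen. For 8609 and 8484 genes the 95% interval of the shift lay within 2-fold.

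Among gene lists in this shift, snoRNA hosts had a median of -0.20 in the mEx5 rescue, below 0 for 12 of 12, and 0.37 in the pEx5 rescue, above 0 for 12 of 12, with 0 called by edgeR in either. The mEx5 camera adjusted p was 0.019, 0.89 with an estimated correlation and 0.11 without nuclear mEx5 knockdown replicate 2, 0.12 without nuclear mEx5 rescue replicate 2, 0.11 without cytoplasmic mEx5 knockdown replicate 2, 0.11 without cytoplasmic mEx5 rescue replicate 2, 0.15 with all 35 libraries in one fit and 0.099 with the control-ratio trend taken out. The pEx5 camera adjusted p was 9.1e-08, 0.74 with an estimated correlation and 0.13 without cytoplasmic pEx5 knockdown replicate 1. Tested as a difference between the rescues, the median was 0.53 (camera adjusted p = 6.2e-13, and 0.19 with an estimated correlation). Zinc finger genes had a median of -0.11 in the mEx5 rescue. Their camera adjusted p was 7.5e-05, 0.89 with an estimated correlation and 0.98 without nuclear mEx5 knockdown replicate 2 and 0.062 without cytoplasmic mEx5 knockdown replicate 2. Respiratory chain mRNAs had a median of 0.22 in the pEx5 rescue. Their camera adjusted p was 0.0038, 0.97 with an estimated correlation and 0.57 without nuclear pEx5 knockdown replicate 2, 0.046 without nuclear pEx5 rescue replicate 1 with the opposite sign, 0.13 without cytoplasmic pEx5 knockdown replicate 1, 0.14 without cytoplasmic pEx5 rescue replicate 1, 0.63 with length and GC trends taken out, 0.62 with these trends taken out and the replicate block and 0.084 with the control-ratio trend taken out. For the difference between the rescues in this shift, edgeR called 0 genes, with 94 at an unadjusted p under 0.05 where 462 would be expected by chance. DESeq2 called 1, the pseudogene Rpl10a-ps1 at 2.10 (DESeq2 adjusted p = 0.035). The 95% interval of this difference lay within 2-fold for 7319 genes.

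With the replicate number as a block, further lists passed camera for these shifts with 0 members called by edgeR in the fit without the block. Ribosomal protein mRNAs passed in the mEx5 rescue with a median of -0.11 (adjusted p = 0.044, against 0.24) and in the pEx5 rescue with a median of 0.09 (adjusted p = 0.031, against 0.10). In the pEx5 rescue, histone genes passed at 0.39, mitochondrial transcripts at 0.24, mRNA export factors at 0.12, intronless genes at -0.11 and zinc finger genes at -0.07. Their camera adjusted p-values were 0.0046, 0.045, 0.028, 0.028 and 0.044, against 0.064, 0.13, 0.064, 0.081 and 0.081. For the difference between the rescues, mitochondrial transcripts passed at 0.38 and histone genes at 0.22 (adjusted p = 0.0041 and 0.018, against 0.064 and 0.14). With the block and an estimated correlation none of these passed: the adjusted p was 0.88 for ribosomal protein mRNAs in the mEx5 rescue. In the pEx5 rescue it was 0.95 for ribosomal protein mRNAs, and for the other lists, in the order given, 0.52, 0.95, 0.52, 0.95 and 0.95. For the difference they were 0.92 and 0.92.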

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

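Lists and rules were set before the data were examined, and the length, GC and control-ratio corrections, the correlations with transcript length and GC, and the genes outside the count table were chosen after the result was seen. A test of the difference of the knockdown between the lines, pEx5 minus mEx5, picked out 9 lists in total lysate, with 0 members called by edgeR. Cell division (G2/M) genes were above 0 for 26 of 26 (median 0.13, camera adjusted p = 5.3e-06, and 0.19 with an estimated correlation), and neuronal genes below 0 for 18 of 24 (median -0.09, camera adjusted p = 0.0014, and 0.14 with an estimated correlation). Both held without each library. Endoplasmic reticulum chaperones (median -0.11, camera adjusted p = 0.0038, and 0.19 with an estimated correlation) had 0.11 without total pEx5 control replicate 2 and 0.062 without total pEx5 knockdown replicate 2. Interferon genes (median 0.15, camera adjusted p = 0.0030, and 0.19 with an estimated correlation) had 0.11 without total pEx5 control replicate 1 and 0.064 without total pEx5 knockdown replicate 2. Cholesterol genes (median -0.09, camera adjusted p = 0.016, and 0.91 with an estimated correlation) had 0.46 without total mEx5 control replicate 1, 0.18 without total mEx5 knockdown replicate 2, 0.86 without total pEx5 control replicate 2, 0.055 without total pEx5 knockdown replicate 1 and 0.058 without total pEx5 knockdown replicate 2. Noradrenergic neuroblastoma genes (median -0.15, camera adjusted p = 0.016, and 0.50 with an estimated correlation) had 0.053 without total mEx5 control replicate 1, 0.75 without total mEx5 knockdown replicate 2, 0.23 without total pEx5 control replicate 2 and 0.24 without total pEx5 knockdown replicate 1. SR and hnRNP protein genes (median -0.06, camera adjusted p = 0.043, and 0.94 with an estimated correlation) had 0.61 without total mEx5 control replicate 2, 0.81 without total mEx5 knockdown replicate 1, 0.82 without total pEx5 control replicate 1 and 0.55 without total pEx5 knockdown replicate 2 with the opposite sign. Noncoding snoRNA hosts (median 0.22, camera adjusted p = 0.037, and 0.94 with an estimated correlation) had 0.46 without total mEx5 control replicate 1, 0.41 without total mEx5 knockdown replicate 2 with the opposite sign, 0.80 without total pEx5 control replicate 2 and 0.73 without total pEx5 knockdown replicate 1. Intronless genes (median -0.09, camera adjusted p = 0.037, and 0.19 with an estimated correlation) had 0.078 without total mEx5 control replicate 2, 0.096 without total mEx5 knockdown replicate 1, 0.18 without total mEx5 knockdown replicate 2, 0.11 without total pEx5 control replicate 1, 0.15 without total pEx5 control replicate 2, 0.060 without total pEx5 knockdown replicate 1, 0.16 without total pEx5 knockdown replicate 2, 0.099 with all 35 libraries in one fit, 0.38 with length and GC trends taken out and 0.082 with these trends taken out and the replicate block.

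A test of the difference between the rescues, which does not separate isoform from line, picked out 5 lists. In total lysate these were ribosomal protein genes (median 0.25, camera adjusted p = 1.1e-10, and 0.93 with an estimated correlation) and respiratory chain genes (median 0.19, camera adjusted p = 1.3e-07, and 0.93 with an estimated correlation). The first had 0.41 without total mEx5 knockdown replicate 1 and 0.27 without total pEx5 rescue replicate 1, and the second 0.15 without total mEx5 knockdown replicate 1 and 0.13 without total pEx5 rescue replicate 1. In the nuclear to cytoplasmic shift, snoRNA hosts had a median 0.53, camera adjusted p = 6.2e-13, and 0.19 with an estimated correlation, and held without each library. Ribosomal protein genes (median 0.14, camera adjusted p = 0.0063, and 0.89 with an estimated correlation) had 0.91 without nuclear mEx5 knockdown replicate 1, 0.94 without nuclear mEx5 rescue replicate 2 with the opposite sign, 0.25 without nuclear pEx5 knockdown replicate 2, 0.089 without nuclear pEx5 rescue replicate 1 with the opposite sign, 0.18 without cytoplasmic mEx5 rescue replicate 2, 0.11 without cytoplasmic pEx5 knockdown replicate 2, 0.94 with length and GC trends taken out with the opposite sign, 0.82 with these trends taken out and the replicate block and 0.16 with the control-ratio trend taken out. Respiratory chain genes (median 0.27, camera adjusted p = 2.6e-04, and 0.89 with an estimated correlation) had 0.60 without nuclear mEx5 knockdown replicate 1, 0.17 without nuclear mEx5 rescue replicate 2, 0.19 without nuclear pEx5 knockdown replicate 2, 0.52 without nuclear pEx5 rescue replicate 1 with the opposite sign, 0.18 without cytoplasmic mEx5 rescue replicate 2, 0.16 with length and GC trends taken out and 0.16 with these trends taken out and the replicate block. The difference between the rescues in total lysate had a Spearman rho of -0.59 with transcript length across genes. For nuclei, edgeR with the replicate block called 159 genes for a difference of the knockdown between the lines, against 0 without the block, where 604 had an unadjusted p under 0.05 and DESeq2 called 1. This difference had a rho of 0.46 with transcript length and -0.43 with GC, and with these trends taken out the block called 46.

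Some genes outside the count table lay above their control level after knockdown, in RPKM of total lysate (n = 4 libraries per condition, no test). Hist2h3c1, a histone H3 gene, had a mean of 1.78 (SD 0.47) against 0 in all 4 control libraries, and 1.79 in the rescues. The small heat shock gene Hspb7 had 1.60 against 0.040, and 1.17 in the rescues. Magea8 had 1.08 against 0.048, and 0.94 in the rescues, and Rasl2-9 1.98 against 0.18, and 1.29 in the rescues. These 4 genes were chosen after their values were seen.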

How the results depend on the processing

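No named gene that was called changed sign, nor did a median of the knockdown genes followed in the rescues, and list calls that did are given beside them. With library totals alone the balance of calls turned from 354 rises and 121 falls to 206 and 411 in the knockdown shift, and from 1832 and 1931 to 2277 and 1547 in cytoplasm. Of the main results under each alternative 459 stayed, 37 moved and 1 grew weaker, and of the others 274 stayed and 95 moved. The cause was not tested. With the replicate block the knockdown raised 2902 and lowered 2904 genes in total lysate, from 1973 and 2084. In cytoplasm it raised 2212 and lowered 2357, from 1832 and 1931. Both counts grew by less than 1.5-fold and so are among those that stayed. With this block the nuclear knockdown count became 5123, the shift 1188, the rescues in total lysate 62 (mEx5) and 3 (pEx5), and 64 in place of 46 list calls passed. It also moved per-line counts, gave 84 and 17 for the rescues in nuclei and 2 and 2 in cytoplasm, and 159 for nuclear line differences. With each culture as a block, the knockdown shift fell to 296 rises and 54 falls, from 354 and 121. In the mEx5 line it fell to 37 and 5, from 60 and 18. Of 220 calls of named genes, 31 were lost with this block. The pEx5 rescue shift had 1 call with it. All 35 libraries in 1 fit gave 787 for the knockdown shift, 2 for the pEx5 rescue and 1 for its shift. DESeq2 gave 792 for the knockdown shift, 8 and 3 for the rescues, 2 and 3 for their shifts and 1 for the difference of these. Chosen after seeing the data, length and GC trends taken out gave 1068 for the knockdown shift and 2 for either rescue. With the block as well, the knockdown gave 6122 in total lysate, 5483 in nuclei and 1918 for the shift, the rescues 22 and 3, and their shifts 2 and 2. Without genes that hold GAAAACT, also chosen then, the shift gave 275.

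Without 1 library, counts ranged from 3078 to 4080 for the knockdown in total lysate, 2009 to 3035 in nuclei, 2866 to 4383 in cytoplasm and 6002 to 6558 between control fractions. The knockdown shift ranged from 172, without cytoplasmic mEx5 knockdown replicate 1, to 544, and either rescue shift from 0 to 1. Passing pairs of list and contrast within a fit ranged from 0 to 31. The median of genes lower in knockdown ranged in the pEx5 rescue from 0.0051, without pEx5 knockdown replicate 1, to 0.16, without its replicate 2. Leaving out the lone cytoplasmic pEx5 control removes its group, so contrasts with it have no value. With library totals alone, the median shift of the mEx5 knockdown moved by -0.12. Small changes were often missed: in simulated data 36% of 1.5-fold changes were found for the knockdown shift and 12% for the pEx5 rescue shift. The chi-square per degree of freedom between replicates was 14.9 to 64.0, where counting error alone gives 1.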

Other observations

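Outside the count table, Pyy (peptide YY) had 1.46 RPKM in total lysate after knockdown against 29.9 in control, and Ppy (pancreatic polypeptide) 1.07 against 18.5 (n = 4 libraries each, no test). Control means in the mEx5 and pEx5 lines were 50.8 and 9.02 for Pyy and 31.7 and 5.31 for Ppy. Galnt15, a glycosyltransferase, had 0.41 against 2.12 and 5.39 in the controls of the lines, and the adhesion molecule Madcam1 0.18 against 2.27 and 1.17. Of 5282 such genes that reached 1 RPKM, 964 lay above and 522 below all controls in every knockdown library, or 28.1% where chance gives 2.86%. These genes were chosen after their values were seen. The control libraries of the lines were also compared in total lysate: edgeR called 0 genes, with 706 at an unadjusted p under 0.05 and with the replicate block 213 were higher and 104 lower in pEx5.

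Of the tests below, those on Chtop restoration, the 2 corrections for purity, the sample splits, the iCLIP marks and the reversal of genes without GAAAACT were chosen only after the result was seen. The knockdown called 4057 genes in total lysate over both lines, or 2187 in mEx5 and 2357 in pEx5 alone. Each rescue, with 2 against 2 libraries, called Chtop alone against its knockdown. In simulated data the pEx5 rescue test found 58% of 1.5-fold changes, so few calls do not show that few changes were reversed. Rescue against control called 1735 genes in mEx5 and 1767 in pEx5. For these changes an off-target effect of the siRNA was set against loss of Chtop. The 7-base sequence with the lowest change, GAAAACT, had t = -17.7 and lies in Chtop, as seed matches of the siRNA acting on 3' UTRs would give. Genes with this exact sequence were not the whole change, since 42.9% of genes without it were called. Genes without it can still hold the overlapping AGAAAAC (t -11.0) or AAAACTA (t -10.2). This share therefore does not limit off-target effects of the siRNA through other matches. Unrestored Chtop RNA was excluded by the log2 value of 0.52 against control, and length and GC trends by the 96.8% of calls that stayed with them taken out. If changes of genes without GAAAACT came from loss of Chtop, the rescues would reverse them more than those with it, but median changes without minus with it were -0.057 (mEx5) and 0.022 (pEx5) for genes lower in the other line's knockdown, where reversal is upward, and -0.058 and 0.013 for genes higher, where it is downward. With length and GC held fixed these were 0.017 (SE 0.0098) and 0.029 (SE 0.0084) for genes lower and 0.016 (SE 0.014) and 0.017 (SE 0.012) for genes higher, so loss of Chtop stayed open for these genes.

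With TMM scaling more genes rose than fell in nuclear to cytoplasmic ratio after knockdown, 354 against 121, but with library totals alone 206 rose and 411 fell, so the sign of this balance hung on scaling, and fraction purity and retention were weighed only for the TMM balance. The Spearman correlation of the shift with the control ratio left purity open, at -0.17 in mEx5 and 0.33 in pEx5, as did its correlation with the change in total level for that change, at -0.18. With the control-ratio trend taken out, 84.2% of the genes with a rise stayed called, so purity was not behind most single calls. The rises then numbered 369 and the falls 296, so the drop to 31.3% of the surplus came from more falls and not from fewer rises, and purity stayed open for the surplus. Genes with GAAAACT shifted by 0.15 more than others, consistent with loss of seed-matched transcripts from the cytoplasm as part of the rise.

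Genes marked for Chtop iCLIP overlap in the authors' deposited table (4484 genes) were tested for a move toward the nucleus after knockdown. Their median shift was -0.023 against 0.042 for other genes, and with covariates the difference in shift was 0.0037 (t 0.56) with straight-line covariates and 0.014 (t 2.15) with curves over 8633 genes, so the outcome depended on the model and was left open. In the rescues the shift was lower in marked than in other genes in both models. The difference was -0.024 (t -5.25) and -0.033 (t -7.99) in mEx5 and -0.025 (t -5.20) and -0.028 (t -6.29) in pEx5. The rescues differed by -6.1e-04 (t -0.093) and 0.0050 (t 0.92). All these t values take genes as independent and do not measure the spread between libraries. No library was left out and no replicate block was fitted here, so a small drift between libraries is not separated from rescue. In total lysate, marked genes differed from others by 0.061 (t 16.5) and 0.057 (t 16.5) in the mEx5 rescue and by 0.0073 (t 2.50) and 0.0070 (t 2.60) in pEx5. The difference between the rescues was -0.054 (t -15.0) and -0.050 (t -15.5), with the same limits. The mEx5 rescue in total lysate had a Spearman rho of 0.51 with transcript length, a covariate here. The pEx5 medians without covariates were 0.0026 for marked and 0.017 for other genes. Under control siRNA marked genes were more nuclear by 0.38 (t 22.9) and 0.40 (t 26.2) in the same models.

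The libraries of each comparison, or its cultures for the shift, were also split in every other way into groups of the same sizes, 35 splits each, with the lines pooled and the other groups kept in the fit. In total lysate the real split called 4008 genes and the highest other 0, in nuclei 2783 and 4, in cytoplasm 3876 and 2053, in the shift 545 and 0, and between control fractions 6519 and 5425. The highest other split put 1 knockdown library with the controls in cytoplasm, and 1 nuclear library with the cytoplasmic ones between control fractions. In each case 1 split, the real one, called as many, which excludes a chance split only if replicate numbers are left aside, since these splits mixed them and fitted no block. Of the 18 splits that kept the numbers balanced, fitted with the block, the real one called 5172 and the highest other 5 in total lysate. These were 4109 and 10 in nuclei, 4534 and 2305 in cytoplasm, 1042 and 0 in the shift, and 6895 and 5191 between control fractions. With 18 splits a share under 0.05 cannot be reached.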
